A study of Homo sapiens with 15 samples.

How the data were processed

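Libraries of CT27, an established human trophoblast stem cell line, were made after transduction with lentivirus carrying a control hairpin or 1 of 2 DNMT1 hairpins, from undifferentiated hTSC (6 libraries) and from cells taken to EVT (9 libraries). The deposited table gives 1 whole-number count per gene and library. Per the submitters' processing notes the tools included Trim Galore 0.6.11, HISAT2 2.2.1, SAMtools 1.16.1, featureCounts, edgeR 4.4.2 and limma 3.62.2 with build hg38. Their roles, the annotation, the strand setting and the rule of the low-count filter are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. The deposited values are called normalized, but behave as raw counts: no whole number below 200 is missing in any library, where scaling up by 5% leaves 10 missing. Scaling down by as much leaves none missing, but the scatter of the number of genes per value around its running mean, relative to counting noise, was 0.82 to 1.2 as deposited and 1.58 to 2.34 after scaling down. Other factors were not tried. The values were tested as counts. The design fixed before the data were examined named limma on log values for normalized values and edgeR for counts, and the edgeR branch was used.

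Library totals ran from 21904030 to 32308047 counts. The total of hTSC shRNA B replicate 2 came to exactly 23800000, with MRPL23 at 1097 counts there and 144 to 451 in the other 14 libraries. Its origin is not known, the values were used as deposited, and the effect of leaving the library out is given in the closing section. Gene symbols were found for 18587 of the 18930 identifiers (98.19%), and 18559 were in GENCODE 29, the source of coordinates (GRCh38), with 14218 protein-coding genes. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 2.45 to 8.20), so none was merged.

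The test was edgeR 4.0.16 quasi-likelihood (R 4.3.3) with TMM scaling, 1 mean for each of the 6 groups over all 15 libraries and 9 residual degrees of freedom, two-sided, at a Benjamini-Hochberg adjusted p below 0.05 over 18930 genes. The biological coefficient of variation was 5.29%. Knockdown means the average of both hairpins minus control. SE is the absolute log2 fold change divided by the square root of the F statistic. CPM are counts divided by the TMM-scaled library size, as edgeR gives them, given as mean ± SD. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over lists within a comparison, for lists of at least 5 measured genes.

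There were 25 lists fixed before the data were examined: trophoblast stem, EVT and STB markers, germline, X-linked cancer-testis, imprinted, interferon, p53, proliferation, DNA methylation machinery, retroviral-derived, mesenchymal, keratin and junction, immediate early, hypoxia, pluripotency, amnion, stromal, endothelial, immune, neuronal, mitochondrially encoded, KRAB-type zinc finger, histone and ribosomal protein genes. A squamous list and a class I antigen presentation list were added later. Named genes were chosen by a rule set before the data were examined: DNMT1, the 10 largest rises and 10 largest falls of each knockdown comparison with a mean of at least 5 counts and no overlap of knockdown and control libraries, the 5 largest in each direction of the other comparisons, and up to 4 members of each list. A group without a count was set at a floor of 3 counts over the group, and ratios on 1 to 3 counts have exact 95% counting intervals.

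The scripts were tested on simulated counts for 18930 genes, 18730 of them unchanged in each comparison. In the simulated hTSC comparison edgeR recovered 56.72% of 1.5-fold, 83.58% of 2-fold and 89.39% of 4-fold changes, with 10 of 163 calls false. In the simulated EVT comparison it recovered 74.63%, 85.07% and 95.45%, with 13 of 183 false. Alternatives were median-of-ratios scaling, quantile scaling in limma voom, limma voom with sample weights, DESeq2 1.42.0 and edgeR without a trend of the spread with the mean. Others were a filter at a mean of 5, fits within a state, a replicate block, a 2-fold threshold and leaving out each library. Library size as the only scaling, a filter at 1 CPM and protein-coding genes alone were added after the data were seen.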

Results

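RNA was sequenced from 15 libraries of CT27, an established human trophoblast stem cell (hTSC) line, after lentiviral knockdown of DNMT1, the maintenance DNA methyltransferase that copies methylation to newly made DNA. There were 6 groups. Undifferentiated hTSC carried a control hairpin, DNMT1 shRNA A or DNMT1 shRNA B, with 2 libraries each. Cells taken through a differentiation protocol to extravillous trophoblast (EVT), the placental cell type that invades the uterus, carried the same hairpins, with 3 libraries each. The table held counts for 18930 genes, and library totals ran from 21904030 to 32308047 counts. The total of hTSC shRNA B replicate 2 was exactly 23800000, and no other library had a total rounded like that. All libraries were listed with puromycin at 1 ug/mL for 4 days from day 2 and with 0.8 mM valproic acid (VPA). The hTSC were collected on day 13 after transduction, and the EVT protocol took 8 days. All hTSC libraries belonged to batch 1 and all EVT libraries to batch 2. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

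DNMT1 (ENSG00000130816, GRCh38 chromosome 19, 10133345 to 10231286, minus strand) was lower in every knockdown library than in every control of its state. In hTSC it was at 180.7 ± 0.952 CPM (counts scaled to library size; SD, n = 2) in controls, 20.6 ± 1.31 with shRNA A and 54.7 ± 1.61 with shRNA B. In EVT it was at 147.5 ± 13.8 CPM (SD, n = 3) in controls, 43.9 ± 0.775 with shRNA A and 56.8 ± 2.08 with shRNA B. The log2 fold change over both hairpins was -2.43 (SE 0.06) in hTSC, with an adjusted p of 9.81e-22 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In EVT it was -1.56 (SE 0.05, adjusted p = 2.03e-20, edgeR). DNMT1 was lower with shRNA A than with shRNA B in both states, by a log2 difference of -1.40 (SE 0.08, adjusted p = 4.20e-14, edgeR) in hTSC and -0.37 (SE 0.06, adjusted p = 2.69e-05, edgeR) in EVT.

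**Figure D1:**
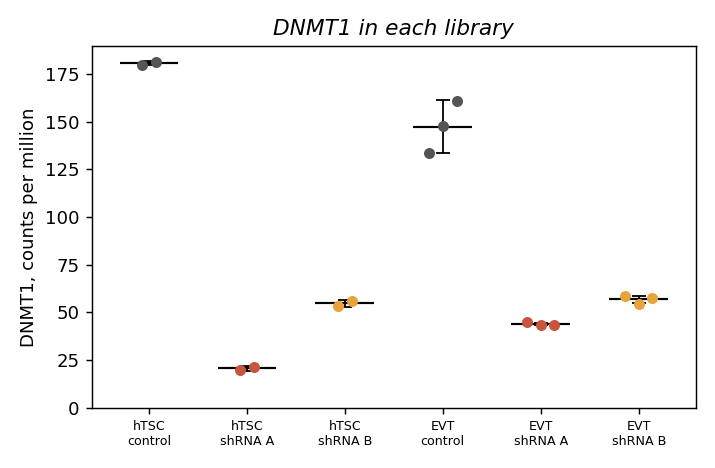
DNMT1 in CPM (vertical axis) in the 6 groups (horizontal axis), with a point per library, a line at the group mean and bars of 1 SD. Control means were 180.7 in hTSC and 147.5 in EVT, and knockdown means lay between 20.6 and 56.8.

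The first comparison asked what loss of DNMT1 changed in undifferentiated hTSC. Interferon-response genes, which cells switch on against viruses, rose nearly as a block: 48 of 55 measured members were higher in knockdown and 1 was lower. IFI27, an interferon-induced mitochondrial protein (ENSG00000165949, GRCh38 chromosome 14, 94104836 to 94116698), went from 0.882 ± 0.102 CPM (SD, n = 2) in controls to 259 ± 20.3 with shRNA A and 13.0 ± 1.01 with shRNA B. Genes of the cell cycle moved the other way, with 43 of 44 proliferation genes lower and none higher. MCM2, a subunit of the replicative helicase, fell from 140 ± 3.98 CPM to 34.3 ± 0.731 with shRNA A and 77.2 ± 2.12 with shRNA B. Across all genes, edgeR called 4603 higher and 4681 lower at an adjusted p below 0.05, of which 1311 and 518 differed at least 2-fold.

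The interferon list had a median log2 fold change of 1.76, or 1.67 with the genes absent from controls set at their bound (camera adjusted p = 5.43e-31). The call held with an estimated correlation (adjusted p = 0.0117). OAS1, a sensor of double-stranded RNA, rose by 4.82 on the log2 scale (SE 0.42, edgeR adjusted p = 1.63e-10), and MX1, an antiviral GTPase, by 3.75 (SE 0.19, edgeR adjusted p = 2.18e-15). SAMD9L, an antiviral factor, had no count in the hTSC controls and was at least 16.2-fold higher in knockdown. The proliferation list had a median of -1.003 (camera adjusted p = 1.77e-52, or 0.00855 with an estimated correlation). Besides MCM2, GINS2, another part of the helicase, fell by 1.54 on the log2 scale (SE 0.08) and the mitotic kinesin KIF20A by 1.36 (SE 0.07). Of 36 p53 target genes 27 rose and 3 fell (camera adjusted p = 4.63e-11, or 0.00855 with an estimated correlation). The death receptor FAS changed by 2.54 (SE 0.26), the stress cytokine GDF15 by 1.46 (SE 0.07) and the protease inhibitor SERPINE1 by 1.45 (SE 0.05).

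Genes of other trophoblast and structural programmes also rose. Of 43 syncytiotrophoblast (STB) markers, genes of the fused, hormone-secreting placental layer, 24 were higher and 5 lower (median 0.46, camera adjusted p = 4.63e-11, or 0.0419 with an estimated correlation). The rise of the list came from shRNA A, with 34 higher and 3 lower (median 1.34). With shRNA B 16 were higher and 13 lower, with a median of 0 and no call (camera adjusted p = 0.0735, or 0.562 with an estimated correlation). The pregnancy-specific glycoproteins PSG1, PSG6 and PSG2 rose by 2.45, 2.21 and 2.07 on the log2 scale, and were called higher with each hairpin, though near-identical family members can share reads. Of 24 mesenchymal genes 13 rose and 2 fell (camera adjusted p = 5.58e-06, or 0.02 with an estimated correlation). INHBA, which encodes an activin subunit, rose by 3.17 (SE 0.17) and the smooth muscle actin gene ACTA2 by 2.74 (SE 0.24). Of 31 replication-dependent histone genes, which share reads among copies, 11 rose and 1 fell (camera adjusted p = 0.00537, or 0.0304 with an estimated correlation), among them H2BC5 (2.28) and H1-2 (1.99). Signs of a different library makeup are given further below, and their part in this rise was not tested. In the list of DNA methylation machinery 20 of 35 genes fell and 4 rose (camera adjusted p = 3.29e-06, or 0.02 with an estimated correlation). DNMT1, the target of the hairpins, is among those that fell, and the list was not tested without it. Besides DNMT1, the de novo methyltransferase DNMT3B fell by 1.15, UHRF1, which brings DNMT1 to hemimethylated DNA, by 1.06, and the demethylating enzyme TET1 by 1.07. With shRNA B alone the mesenchymal, methylation and histone lists were called with the preset correlation and lost with an estimated one (adjusted p = 0.0822, 0.0822 and 0.0794).

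A second set of lists was called with the preset correlation and lost with an estimated one. Of 29 keratin and epithelial junction genes 21 rose and 5 fell, with KRT6A changing by 3.56 and CLDN3 by 1.67 (camera adjusted p = 6.47e-06, and adjusted p = 0.0595 with an estimated correlation, or 0.0232 with shRNA A alone). Of 79 ribosomal protein genes 66 fell and 1 rose (camera adjusted p = 5.59e-10, and adjusted p = 0.322 with an estimated correlation), with RPL22L1 at -0.97. Of 15 mitochondrially encoded genes 13 rose, MT-CO1 by 0.62 (camera adjusted p = 8.24e-05, and adjusted p = 0.322 with an estimated correlation). Of 488 zinc finger genes with KRAB-type symbols 176 fell and 38 rose (camera adjusted p = 0.00975, and adjusted p = 0.232 with an estimated correlation). Of 28 immediate early genes 16 rose, JUNB by 1.55, and 7 fell (camera adjusted p = 0.00813, and adjusted p = 0.277 with an estimated correlation). Of 34 EVT markers 15 rose, EBI3 by 2.35, and 8 fell (camera adjusted p = 0.00208, and adjusted p = 0.277 with an estimated correlation). NOTUM, a secreted Wnt inhibitor on that list, was at 24.4 and 29.9 CPM in the controls, 14.4 and 2.53 with shRNA A, and 19.8 and 3.71 with shRNA B. Of 6 pluripotency genes 3 fell, LIN28A by 1.37, and none rose (camera adjusted p = 0.00524, and adjusted p = 0.107 with an estimated correlation).

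The other lists were not called by camera in hTSC for the average of the hairpins. Members went both ways among 30 trophoblast stem genes (10 higher, 12 lower), 50 imprinted genes (13 and 15), 33 X-linked cancer-testis genes (14 and 9), 30 germline genes (8 and 5) and 26 retroviral-derived genes (9 and 8). The same held for 24 hypoxia genes (9 and 6), 13 stromal markers (4 and 5), 12 amnion markers (7 and 4), 13 neuronal genes (4 and 2) and 7 endothelial markers (4 and 1). With a single hairpin camera called amnion (up, adjusted p = 0.0426) and stromal markers (down, adjusted p = 0.0373) under shRNA B and endothelial markers (up, adjusted p = 0.0153) under shRNA A, none with an estimated correlation. Among stem genes the transcription factors HAND1 and CDX2 fell by 1.97 and 2.27, and ELF5 rose by 0.96. Of the retroviral-derived genes PEG10, which is needed for placental growth, fell by 1.54. MAEL, of the piRNA pathway, had 3 counts over the controls and was 50.9-fold higher in knockdown (95% counting interval 17.3 to 248.3), and the cancer-testis gene PAGE2 rose by 4.06. All 4 immune markers rose, too few for a set test, with CD74 changing by 0.78 and CSF1R by 0.60. Adjusted over the list alone, the interferon counts stayed 48 and 1, proliferation became 0 and 44, p53 targets 28 and 3, and STB markers 24 and 6.

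The largest rises by the rule for named genes were in genes close to absent from controls. Besides SAMD9L, genes without a control count were at least 17.1-fold higher (PAGE2B), 16.5-fold (RTP3), 14.02-fold (SPACA7BP), 7.79-fold (IL17C), 5.92-fold (SLC5A1), 3.89-fold (ABI3BP) and 3.27-fold (DKK2). AIM2, a sensor of cytosolic DNA, had 1 count over the controls and 190 over the knockdown libraries, an 88.8-fold ratio (95% counting interval 15.8 to 3525). COL6A3, a collagen VI chain (ENSG00000163359, GRCh38 chromosome 2, 237324003 to 237414375), fell from 80.3 ± 0.788 CPM (SD, n = 2) to 8.21 ± 0.435 with shRNA A and 4.74 ± 0.356 with shRNA B (log2 -3.69, SE 0.09, edgeR adjusted p = 3.57e-22). The ephrin receptor genes EPHA4 and EPHB1 fell by 3.33 and 3.41, PRRT4 by 3.619, CTXND1 by 4.46, SLC6A19 by 3.36 and the pseudogene ADAMTS7P3 by 4.21. GABRP went from 48 counts over the controls to 2, a 51.4-fold ratio (interval 13.5 to 436.2). MAGEA2 and MAGEA2B, near-identical copies that share reads, fell by 4.74 and from 19 counts to 3. Without hTSC control replicate 2, DKK2 (adjusted p = 0.056) and MAGEA2B (adjusted p = 0.424) were no longer called by edgeR. Their adjusted p ran from 0.000658 to 0.056 and from 0.000156 to 0.424 over the alternatives. Intervals and floors (3 counts over the group) cover counting error only.

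The second comparison asked what loss of DNMT1 changed in cells put through EVT differentiation. The genes that mark EVT fell: 31 of 34 measured EVT markers were lower in knockdown and 2 were higher, with a median log2 fold change of -2.21. NOTUM (ENSG00000185269, GRCh38 chromosome 17, 81952507 to 81961840) went from 1309 ± 21.0 CPM (SD, n = 3) in controls to 108 ± 11.9 with shRNA A and 116 ± 34.5 with shRNA B. STB markers fell as well, with 36 of 43 lower and 5 higher. All 43 were higher in EVT controls than in hTSC controls (median 4.82, against 3.91 for EVT markers), which also differ in batch. In these cultures the list therefore does not set STB apart from EVT. CSH2, a placental lactogen gene, went from 1201 ± 49.1 CPM to 116 ± 15.5 and 87.1 ± 15.7, with reads that its near-identical copy CSH1 can share. Over all genes edgeR called 4365 higher and 4913 lower, 838 and 869 of them at least 2-fold. With library size as the only scaling 64.27% of calls were higher against 47.05% with TMM, and the median of all genes stood at 0.09.

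The fall of the EVT markers (camera adjusted p = 6.23e-81) held with an estimated correlation (adjusted p = 0.000194). NOTUM changed by -3.55 (SE 0.20, edgeR adjusted p = 7.16e-15), FLT4, a receptor for VEGF-C, by -3.11 (SE 0.09, edgeR adjusted p = 2.09e-21), DIO2, which activates thyroid hormone, by -3.10 (SE 0.09) and LAIR2 by -3.13 (SE 0.28). The fall of the STB markers (median -1.06, camera adjusted p = 7.53e-30) also held (adjusted p = 0.00529 with an estimated correlation), with CSH1 at -3.60 and the noradrenaline transporter SLC6A2 at -2.96. Of 50 imprinted genes 24 fell and 10 rose (camera adjusted p = 0.000144, or 0.0176 with an estimated correlation), and with shRNA B alone the estimated correlation gave an adjusted p of 0.05015. IGF2, a fetal growth factor, fell by 2.10 (SE 0.06), H19 by 1.88 (SE 0.13) and DLX5 by 2.65 (SE 0.08). The list's median was -0.11 and turned to 0.0033 with library size as the only scaling. Of 7 endothelial markers 4 fell and 1 rose (camera adjusted p = 0.000327, or 0.0181 with an estimated correlation), with VWF at -3.01, ESAM at -1.66 and CDH5 at -0.60.

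Proliferation genes were lower in EVT knockdown too, 41 of 44 with none higher (median -0.62, camera adjusted p = 2.47e-17, and adjusted p = 0.074 with an estimated correlation). Cyclin E1 (CCNE1) fell by 1.90 (SE 0.04) and RRM2, a subunit of ribonucleotide reductase, by 1.57 (SE 0.06). Of 36 p53 targets 24 rose and 2 fell (camera adjusted p = 0.000732, and adjusted p = 0.074 with an estimated correlation, or 0.0461 with shRNA B alone), where FAS rose by 1.19 and GDF15 fell by 0.96. Keratin and junction genes were higher in 16 of 29 and lower in 4 (camera adjusted p = 2.08e-05, and adjusted p = 0.074 with an estimated correlation), with KRT6A at 2.50, KRT17 at 1.99 and the desmosomal cadherin DSG3 at 1.94. Of the DNA methylation machinery, tested with the target DNMT1 in the list, 20 of 35 genes fell and 6 rose (camera adjusted p = 0.000989, and adjusted p = 0.074 with an estimated correlation). TET3 fell by 1.58 and the histone methyltransferase EZH2 by 1.08. Mesenchymal genes rose in 13 of 24 and fell in 7 (camera adjusted p = 0.0053, and adjusted p = 0.0892 with an estimated correlation), with THBS1 at 1.61, INHBA at 2.31 and SNAI1 at -1.82. Ribosomal protein genes fell in 70 of 79 (camera adjusted p = 1.07e-14, and adjusted p = 0.288 with an estimated correlation). Hypoxia genes fell in 16 of 24 and rose in 4, with ADM at -0.93 (camera adjusted p = 0.0108, and adjusted p = 0.403 with an estimated correlation), and were not called with shRNA B alone (camera adjusted p = 0.106). Of 6 pluripotency genes 5 fell, LIN28A by 1.33 (camera adjusted p = 0.00471, and adjusted p = 0.0892 with an estimated correlation).

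The interferon list was not called in EVT for the average of the hairpins, with 22 members higher and 16 lower (camera adjusted p = 0.57). With shRNA B 28 were higher and 10 lower, called up with the preset correlation (camera adjusted p = 0.0219, and adjusted p = 0.581 with an estimated correlation), and with shRNA A 15 were higher and 20 lower (camera adjusted p = 0.353). IFI16 rose by 1.197 and SAMD9L by 1.199, and the immunoproteasome gene PSMB9 fell by 1.32. Trophoblast stem genes were higher in 14 of 30 and lower in 9 (camera adjusted p = 0.502), and were called up with shRNA B alone (camera adjusted p = 0.0109, and adjusted p = 0.581 with an estimated correlation). Among them the epithelial adhesion gene EPCAM rose by 1.01 and ITGA2, an integrin of column progenitors, by 1.0537, while TBX3 fell by 1.06. Members of the remaining lists, not called by camera, also went both ways: KRAB-type zinc fingers (101 higher, 90 lower), germline (7 and 7), cancer-testis (9 and 10), retroviral-derived (8 and 11), immediate early (7 and 11), histones (7 and 6), amnion (6 and 4), stromal (4 and 3) and neuronal genes (6 and 2), the last called up with shRNA A alone (camera adjusted p = 0.0411, and adjusted p = 0.103 with an estimated correlation). Such counts move with the scaling: KRAB-type zinc fingers became 165 higher and 46 lower with library size only, and immediate early genes 11 and 8 with library size and 12 and 8 with quantile scaling. Mitochondrially encoded genes were lower in 7 of 15 and higher in none with TMM, lower in 2 and higher in 4 by library size, and lower in 1 and higher in 5 with quantile scaling. Of the 4 immune markers CD74 was higher by 1.1982 and CSF1R lower by 1.09. Adjusted over the list alone, EVT markers stayed at 2 higher and 31 lower and imprinted genes became 12 and 25.

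The largest falls by the rule for named genes included SCUBE1, a secreted and membrane-bound glycoprotein (ENSG00000159307, GRCh38 chromosome 22, 43197283 to 43343388), from 35.5 ± 0.302 CPM (SD, n = 3) to 2.23 ± 0.203 and 3.00 ± 0.548 (log2 -3.78, SE 0.09, edgeR adjusted p = 4.44e-23). The cartilage proteoglycan gene ACAN fell by 3.64, the calcium channel gene CACNA1G by 3.56, SLC16A9 by 3.66, PDE6H by 3.51, FHOD3 by 3.51 and OR7C1 by 3.76. Among the largest rises were the EGF-family ligand AREG, from 1.12 ± 0.364 CPM to 14.1 ± 2.25 with shRNA A and 5.10 ± 1.18 with shRNA B (log2 2.92, SE 0.18, edgeR adjusted p = 5.88e-14), and the transketolase-like gene TKTL1 (3.21, SE 0.19). DMKN, an epidermal secreted protein, rose by 3.12, IGFBP3 by 3.02, S100A14 by 2.58, C6orf15 by 2.68, PRR20G by 2.86, CHILL1 by 2.72 and AIM2 by 2.57. The pseudogene THAP12P8 went from 2 counts over the controls to 82, a 19.1-fold ratio (95% counting interval 5.11 to 159.9).

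**Figure D2:**
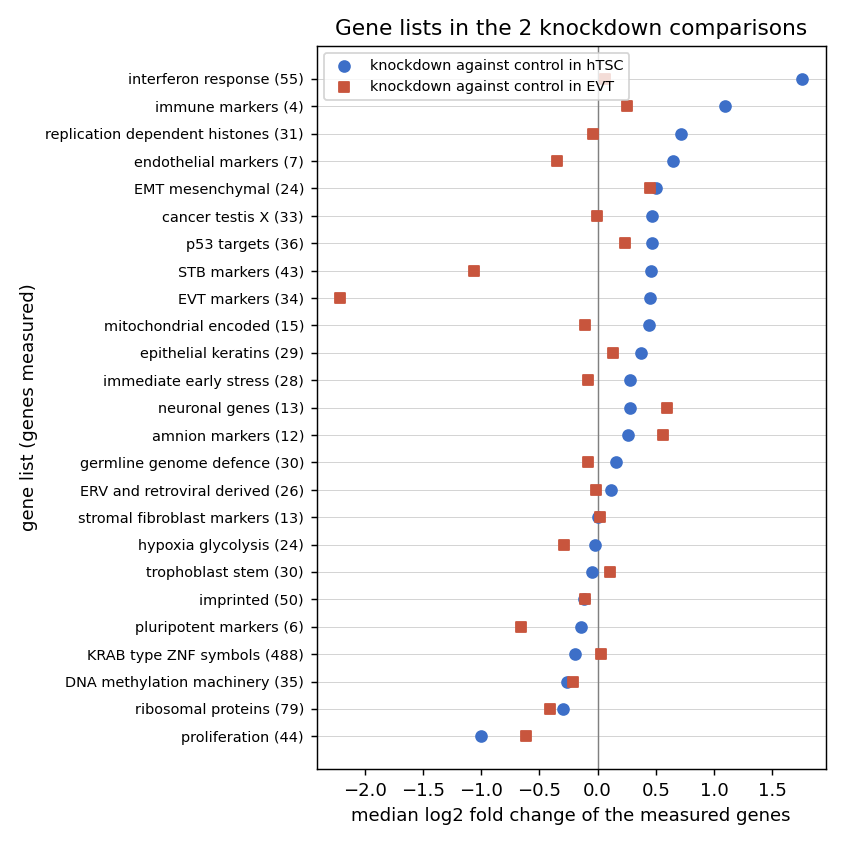
Median log2 fold change of knockdown over control (horizontal axis) for each gene list (vertical axis, genes measured in brackets), circles for hTSC and squares for EVT. The interferon list lies at 1.76 in hTSC and 0.06 in EVT, and the EVT markers at 0.45 and -2.21.

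The third comparison asked whether the knockdown effect differed between the states, by a test of the difference itself (EVT minus hTSC). EVT markers, STB markers and interferon genes responded less positively in EVT than in hTSC: 32 of 34, 38 of 43 and 47 of 55 had a lower effect there. No EVT or STB marker and 2 interferon genes had a higher one. These lists held with an estimated correlation (camera adjusted p = 0.00156, 0.00187 and 0.0152), as did endothelial markers (4 lower, 1 higher, adjusted p = 0.0258) and histones (10 lower, 0 higher, adjusted p = 0.0283). Trophoblast stem genes went both ways, 15 higher and 12 lower, and were not called (median 0.12, camera adjusted p = 0.251). IKZF1, a lymphoid transcription factor, was at 17.8 CPM in hTSC controls and 2.36 and 2.06 in knockdown, against 0.952 in EVT controls and 2.74 and 1.79 in knockdown (log2 difference 4.23, SE 0.25, edgeR adjusted p = 6.22e-14). By edgeR 3849 genes had a higher effect in EVT and 3907 a lower one. With library size as the only scaling 62.77% of calls were higher against 49.63% with TMM, and the median of all genes stood at 0.13. State, batch and culture protocol coincide, so an effect of batch or protocol on the response cannot be told apart from the state.

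Other lists called by camera lost the call with an estimated correlation. Of the p53 targets 19 were lower and 7 higher (adjusted p = 0.0729 with an estimated correlation), of the immediate early genes 15 and 6 (adjusted p = 0.276 with an estimated correlation), of the hypoxia genes 12 and 4 (adjusted p = 0.497 with an estimated correlation), and of the mitochondrially encoded genes 15 and 0 (adjusted p = 0.414 with an estimated correlation). With library size as the only scaling the leaning was gone for hypoxia genes (7 lower, 7 higher) and smaller for p53 targets (16 and 13) and immediate early genes (12 and 9). Proliferation genes were higher in 32 of 44 and lower in 4 (adjusted p = 0.414 with an estimated correlation), and KRAB-type zinc fingers in 158 and 33 of 488 (adjusted p = 0.233 with an estimated correlation). Across genes the fold changes of the states had a Pearson r of 0.235 and a Spearman rho of 0.255, and genes are not independent replicates. Called genes higher in both states numbered 2094 where independent lists give 1061, and lower in both 2009 against 1215. Genes higher in hTSC and lower in EVT numbered 1005 against 1195, and the reverse 610 against 1079.

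**Figure D3:**
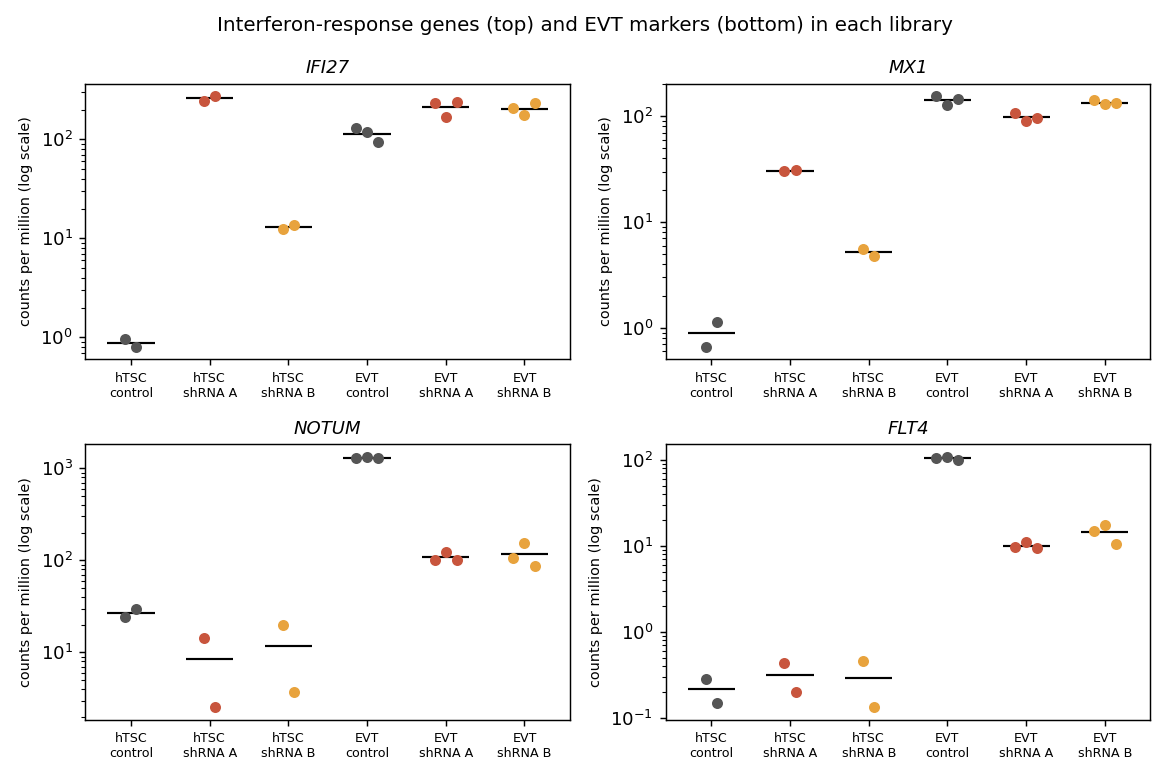
CPM (vertical axes, log scale) of the interferon-response genes IFI27 and MX1 and the EVT markers NOTUM and FLT4 in the 6 groups (horizontal axes), with a point per library and a line at the group mean. IFI27 rose from 0.882 in hTSC controls to 259 with shRNA A and 13.0 with shRNA B, and NOTUM fell from 1309 in EVT controls to 108 and 116.

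The hairpins were also compared with each other. In hTSC the hairpin that left less DNMT1 gave larger changes in some of the leading lists: interferon genes were higher with shRNA A than with B in 45 of 55 members and lower in 1 (camera adjusted p = 0.03 with an estimated correlation), and proliferation genes lower in 42 of 44 with none higher (adjusted p = 0.03 with an estimated correlation). STB markers were higher with A in 35 of 43 and lower in 3 (adjusted p = 0.0101 with an estimated correlation). The p53 targets did not follow, with 14 higher and 12 lower with A (adjusted p = 0.33 with an estimated correlation). In EVT the interferon genes went the other way, 33 lower with A and 3 higher (adjusted p = 0.188 with an estimated correlation). Against control, edgeR called 5310 genes higher and 5035 lower with shRNA A in hTSC, 3240 and 3331 with B, 4161 and 4454 with A in EVT, and 4125 and 4731 with B. Between the hairpins it called 4041 and 3656 genes in hTSC and 3071 and 2858 in EVT. Hairpin and remaining DNMT1 level cannot be told apart with these hairpins.

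Both hairpins called the same genes in the same direction in 5146 cases in hTSC and 5919 in EVT. Simulated counts without any changed gene, where both hairpins were set against the same simulated controls, gave a mean of 0 and 0.6. With no changed gene hardly any call can arise, so these means do not bound what shared controls add to real effects. Independent lists would share 908.8 higher and 886 lower genes in hTSC, where 2563 and 2583 were shared, and 906.7 and 1113 in EVT, where 2704 and 3215 were. The covariance of the fold changes was 0.496 in hTSC against 0.142 simulated, and 0.331 in EVT against 0.0424, with correlations across genes of 0.6 against 0.514 and 0.731 against 0.52. The controls, 2 in hTSC and 3 in EVT, were too few to be split with 2 libraries in each part, so part of the excess may come from sharing them. In hTSC the libraries of both hairpins also moved together by replicate number, which the counts of shared genes do not allow for.

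The fourth comparison set EVT controls against hTSC controls. EVT markers were higher in EVT in all 34 cases, STB markers in all 43 and interferon genes in 53 of 55 with none lower (camera adjusted p = 0.00487, 0.000908 and 0.0177 with an estimated correlation). PAEP, the secreted protein glycodelin, went from 1 count over the hTSC controls to 37.0 ± 3.91 CPM (SD, n = 3). Proliferation genes were lower in 42 of 44 and higher in 1 (adjusted p = 0.0171 with an estimated correlation), while histones were higher in 29 of 31 and lower in 1 (adjusted p = 0.0126 with an estimated correlation). By edgeR with TMM 8137 genes were higher and 7494 lower, with a median of all genes of 0.09. Under median-of-ratios scaling the median was 0.11, with 8238 higher and 7394 lower. With quantile scaling lower calls outnumbered higher ones (7775 and 7161, median -0.03), so the side with more calls depends on the scaling. All of these differences are also differences between batches.

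Signs of another library makeup moved with the state. Mitochondrially encoded genes took 7.19% to 8.94% of the counts in EVT libraries and 1.503% to 2.40% in hTSC libraries, with all 15 higher in EVT (median 2.10, camera adjusted p = 0.0994 with an estimated correlation). Within hTSC their share was 1.503% and 1.77% in the controls and 2.03% to 2.40% in the knockdown libraries. Ribosomal protein genes were lower in 72 of 79 and higher in 7 (adjusted p = 0.235 with an estimated correlation). Between 530 and 758 genes were at 0 in an hTSC library and 112 to 190 in an EVT library. The largest rises were the transfer RNA gene MT-TN (at least 493.1-fold), the hormone gene CGB1 (at least 310.6-fold, with near-identical copies), the small nuclear RNA 7SK (2796-fold, counting interval 501.6 to 110500) and its copy RN7SKP209 (at least 93.0-fold). The largest falls were the processed pseudogenes RPL23AP2 (at least 267-fold), KRT18P13 (at least 140.4-fold), GAPDHP72 (at least 133-fold), RPS27AP5 (1980-fold, interval 354.8 to 78260) and KRT8P5 (1228-fold, interval 339.4 to 10150).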

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

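The tests of histone against proliferation genes, of the interferon level in EVT controls and of the order of the hairpins were chosen after the result was seen. Each value below is the knockdown effect in EVT minus that in hTSC on the log2 scale, and was listed because the edgeR test of the difference between the states had an adjusted p below 0.05 (camera for lists). In all, 7756 genes differed. Because state and batch coincide, these differences cannot be told apart from a difference between batches, and fitted values of genes at 0 in the hTSC controls depend on the prior count. DNMT1 itself differed by 0.86.

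List medians were -2.07 for EVT markers, -1.50 for STB markers, -1.75 for interferon genes, -1.20 for endothelial markers and -0.77 for histones. Lists whose call was lost with an estimated correlation had medians of -0.50 for mitochondrially encoded genes, -0.31 for immediate early genes, -0.24 for hypoxia genes, -0.23 for p53 targets, 0.42 for proliferation genes and 0.26 for KRAB-type zinc fingers (adjusted p = 0.414, 0.276, 0.497, 0.0729, 0.414 and 0.233 in this order). Of interferon and immune genes, IFI27 differed by -5.18, SAMD9L by -6.36, OAS1 by -5.07, MX1 by -4.06, IFI16 by -2.46, PSMB9 by -3.08, IL17C by -6.65, CSF1R by -1.69 and CD74 by 0.42. Of trophoblast genes, NOTUM differed by -2.08, FLT4 by -3.63, DIO2 by -1.44, EBI3 by -3.85, CSH1 by -2.18, CSH2 by -2.19, SLC6A2 by -4.66, PSG1 by -1.56, PSG6 by -2.40, PSG2 by -2.12, HAND1 by 2.81, CDX2 by 3.13, ELF5 by -0.96, EPCAM by 0.98, ITGA2 by 1.08 and TBX3 by -0.97. Of imprinted, vascular and retroviral-derived genes, IGF2 differed by -1.52, H19 by -1.91, VWF by -3.67, ESAM by -2.38, CDH5 by -1.20 and PEG10 by 1.08.

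Of cell cycle and stress genes, GINS2 differed by 0.86, MCM2 by 0.55, KIF20A by 0.89, CCNE1 by -1.71, RRM2 by -0.50, FAS by -1.35, GDF15 by -2.42, SERPINE1 by -1.43, JUNB by -2.0, ADM by -1.53, H2BC5 by -1.76, H1-2 by -2.63, RPL22L1 by 0.92 and MT-CO1 by -0.50. Of chromatin and structural genes, DNMT3B differed by 0.98, UHRF1 by 1.43, TET3 by -1.36, INHBA by -0.86, ACTA2 by -1.55, THBS1 by 1.21, SNAI1 by -1.51, CLDN3 by -1.59, KRT17 by 0.59 and DSG3 by 0.65. Of the genes with the largest changes, PAGE2B differed by -5.59, PAGE2 by -2.59, MAEL by -2.78, SPACA7BP by -5.04, RTP3 by -4.63, DKK2 by -3.79, GABRP by 5.91, MAGEA2 by 4.19, MAGEA2B by 3.28, ADAMTS7P3 by 4.17, COL6A3 by 2.75, PRRT4 by 3.18, EPHB1 by 3.70, EPHA4 by 4.33, AREG by 0.70, S100A14 by 0.74, SCUBE1 by -4.05, OR7C1 by -3.46, ACAN by -2.56, CACNA1G by -3.60, PDE6H by -1.77 and FHOD3 by -2.46.

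The first pattern weighed is the rise of interferon genes in hTSC knockdown, which EVT knockdown did not show for the average of the hairpins, although with shRNA B 28 genes were higher and 10 lower there. A response to a single hairpin was argued against, since 38 of 55 genes rose with shRNA B and 49 with shRNA A. A level already high in EVT remains open: the EVT control mean lay above the hTSC knockdown mean for 47 of 55 genes, but those levels come from different batches. A response graded with the remaining DNMT1 may also play a part in hTSC. There 45 genes were higher with A, which left less DNMT1, than with B. In EVT 33 were lower with A, and the order of the hairpins cannot be separated from their identity. The remaining level as the whole cause of the difference between the states is argued against. DNMT1 was at 30.28% of control with shRNA B in hTSC and 29.79% with shRNA A in EVT. Interferon genes were 38 higher and 0 lower in the first (median 1.03), and 15 higher and 20 lower in the second (median -0.04). Those groups also differ in hairpin and batch. A biological role of DNMT1 loss, which the design names, stays open too.

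The second pattern is the fall of EVT markers in EVT knockdown. Undifferentiated cells as the whole cause are argued against: if they made up the 78.44% that the marker fall needs, 133 genes high in hTSC knockdown would rise by a median of 3.26, and they rose by 0.83 (quartiles 0.31 and 1.23). That share would also raise proliferation genes by a median of 1.13, and they stood at -0.62. A smaller share remains possible, since 97 of the 133 genes rose and 5 fell, with a median share of 5.86%, which would lower the markers by only 0.09, and the hTSC profile comes from the other batch. Scaling moved the marker median by at most 0.1133, and less efficient differentiation of the knockdown cells themselves was not tested.

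The third pattern is the fall of processed pseudogenes and the rise of RNAs without poly(A) tails in EVT controls against hTSC controls. Library preparation or read assignment that differed between the batches is a candidate explanation: 782 pseudogenes moved apart from their 426 measured parents by a median of -1.81 (quartiles -3.58 and -0.12). Histones moved apart from the proliferation genes by 5.26, which transcription following the cell cycle would not give. Differentiating cells can also carry tailed histone RNA, so a difference between the states cannot be told apart from the batch.

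The number of genes called was compared with other splits of the EVT libraries in fits of 2 groups. Knockdown against control gave 6813 genes, and 1 of the 84 splits, the real one, gave as many, so chance can be excluded only if the libraries are independent, which the labels do not show. The highest other split gave 2110 and set the shRNA B libraries apart. The 81 splits that mixed groups gave 0, so the count mainly shows that libraries of a group resemble each other, and the 3 splits that kept groups whole are too few for a share under 0.05. For shRNA A against control the real split gave 8756 genes, for shRNA B 8897 and for A against B 5556, with 0 as the highest other, and the 10 splits of each are too few for a share under 0.05, the real split being the 1 as large.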

How the results depend on the processing

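Library size as the only scaling, the filter at 1 CPM and protein-coding genes alone were chosen after the data were seen. Counts of genes stayed within 1.5 times the reported one in 93 pairs of a comparison and an alternative setting. They also did so in all 150 pairs of a comparison and a left-out library. DNMT1 kept its direction and call in 105 pairs of a comparison and a left-out library and in 64 pairs with other settings. The pairs without a library come from 15 fits, and many of these comparisons do not use the library left out. With a 2-fold threshold, which by construction calls fewer genes, the counts were 1829 in hTSC, 1707 in EVT, 1980 for their difference, 9385 for EVT against hTSC controls, 3208 and 1038 for shRNA A and B in hTSC, 1815 and 1948 in EVT, and 1728 and 697 between the hairpins. Lists called fell with an estimated correlation to 7 of 14 in hTSC, 4 of 12 in EVT, 5 of 11 for the difference and 5 of 12 between the controls. Fry, which does not compare a list with other genes, called 17 for the difference and 24 between the controls. In hTSC and EVT knockdown it also called more lists than camera, within 1.5 times as many. The germline list in EVT turned from up to down with fry (adjusted p = 0.0143), and the cause was not tested. The side with more calls turned with the scaling. Higher calls were 47.05% in EVT knockdown against 51.39% with quantile scaling, 49.63% for the difference against 51.19% with median-of-ratios and 56.29% with quantile scaling, 51.33% for shRNA A in hTSC against 46.39% and 46.35%, and 52.5% between the hairpins in hTSC against 46.81% and 46.01%. In EVT they were 48.3% for shRNA A and 46.58% for B against 52.33% and 51.88% with quantile scaling, and 51.8% between the hairpins against 47.59% with median-of-ratios. Among the tests of single lists, quantile scaling lost 3 camera calls and turned the direction of 10 lists without a call. Leaving out a library also changed the call or direction of some lists. Of named genes 45 calls were lost on leaving out a library and 18 in other settings.

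Without a library, counts ran from 7300 to 9355 in hTSC, 8106 to 9464 in EVT, 6358 to 7760 for the difference, 14509 to 15688 between controls, 8728 to 10482 and 4792 to 6662 for shRNA A and B in hTSC, 7648 to 8809 and 7886 to 9020 in EVT, and 6259 to 7771 and 4763 to 6165 between the hairpins. Leaving a group with 1 library assumes that it varies like the others. Without hTSC shRNA B replicate 2, whose total is 23800000, the counts were 8883 in hTSC, 5485 for shRNA B there and 7551 for the difference.

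The labels do not say what replicate numbers mark. In hTSC, where 2 libraries a group make each correlation of deviations appear in mirror image, replicates of the same number correlated at 0.3647 between shRNA A and B, so the knockdown libraries moved together by number, and at 0.0638 and 0.0147 between controls and shRNA A and B. In EVT 1 of 9 same-numbered pairs was above 0.1 (0.2536), and 2 of 18 pairs of different number were, the highest at 0.366. A correlation of the size seen in hTSC thus also arose between different numbers, and its size alone does not show that the number marks something shared. Not every pair being above 0.1, the main fit has no block and treats the libraries of a group as independent. A block, tried next, shifts controls and knockdown of a state alike by number. It cannot hold a shift of the hTSC knockdown libraries alone, so it is no check of that shift. With a replicate block 9410 genes were called in hTSC, 9440 in EVT, 7901 for the difference, 14800 between controls, 10472 and 6792 for shRNA A and B in hTSC, 8761 and 8996 in EVT, and 7866 and 6122 between the hairpins, with DNMT1 at -2.43 and -1.56. Pseudocounts for log values were not run, since counts were tested. The fitted log2 fold changes use a prior count, which was not varied, so its effect on genes near 0 counts was not tested.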

Other observations

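The lists of class I antigen presentation and of squamous genes were chosen after the result was seen, and genes already named were left out of them. Genes of class I antigen presentation, which shows peptides to T cells, rose in hTSC knockdown: 13 of 16 were higher and 2 lower, with a median of 1.044 (camera adjusted p = 0.0133 with an estimated correlation). HLA-B rose by 1.74, the peptide-loading factor TAPBP by 1.65, B2M, the shared light chain, by 0.96 and HLA-E by 0.85, although HLA genes share reads. In EVT knockdown 6 were higher and 7 lower. Among the higher were HLA-B (1.39), HLA-A (1.04) and NLRC5 (1.53), and among the lower HLA-E (-0.54) and B2M (-0.14). The effect was lower in EVT than in hTSC for 13 with none higher (camera adjusted p = 0.0183 with an estimated correlation). For HLA-B the difference was -0.35, and for HLA-A and NLRC5 it was not called (edgeR adjusted p = 0.743 and 0.0709). A rise together with the interferon genes is a hypothesis from these data.

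Squamous epithelium genes were tested because several of the largest rises were of that kind. Of 57 listed genes 38 were measured in these trophoblast cells, 25 higher and 3 lower in hTSC knockdown (median 0.65, adjusted p = 0.0205 with an estimated correlation) and 25 higher and 5 lower in EVT knockdown (median 0.5405, adjusted p = 0.0537 with an estimated correlation). The hTSC rise was stronger with shRNA A (28 higher and 2 lower, median 0.95, adjusted p = 0.0125 with an estimated correlation). With shRNA B 17 were higher and 4 lower (median 0.26), called with the preset correlation (camera adjusted p = 0.00259) and lost with an estimated one (adjusted p = 0.125). In EVT the adjusted p with an estimated correlation was 0.0281 with shRNA A and 0.0857 with shRNA B. A rise in both states may be present, but the EVT test of both hairpins did not pass.

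Some values concern a single library or replicate 2 of both hairpins in hTSC. The total of hTSC shRNA B replicate 2 was exactly 23800000 counts, and MRPL23 stood at 48.5 CPM there against at most 17.5 in the other 14 libraries, with 244 counts in the other library of its group and 1097 in this one. In hTSC, CSH1 was at 8.15 and 14.02 CPM in the controls, 7.07 and 0.0658 in replicates 1 and 2 of shRNA A, and 10.4 and 0.0884 in those of shRNA B. The log ratio of replicate 2 to replicate 1 followed GC content across 10032 genes with a Spearman rho of 0.578 for shRNA A and 0.671 for shRNA B, and -0.0872 for the controls. The hTSC knockdown values, and the differences between the states for genes such as CSH1 and NOTUM, average over these libraries.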
